A study of Caenorhabditis elegans with 2 samples.

How the data were processed

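Binding of the tagged protein LIN-54 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole young adult Caenorhabditis elegans, with 2 biological replicates in 1 group and 1 library per replicate. Per the labels, the animals carried a fosmid transgene that expresses LIN-54 with a C-terminal GFP-FLAG tag, the immunoprecipitation used an anti-GFP antibody, and chromatin was sheared by sonication. Per the submitters' processing notes, the authors listed candidate regions for each replicate and for the pooled replicates from the alignments and a control file, as input to an irreproducible discovery rate (IDR) procedure. Peaks that passed this procedure form the optimal list. The aligner, the peak caller and the IDR threshold are not given in the sources used here. All 4 lists use genome build ce11 (WBcel235), per the labels.

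Each deposited region carries the caller's signal value, which ranks regions within a list and whose formula is not given in the sources used here. Each deposited region also carries a −log10 q value, which reached a single maximum in most strong regions of a list and was therefore not used for ranking. The summit offset gives the position of the maximum within each deposited region. Each relaxed list, of replicate 1, replicate 2 and the pooled replicates, held 30000 regions, and the optimal list held 3449 peaks, called IDR peaks here. Between lists of different origin, signal values were compared by rank or correlation, and otherwise only printed or plotted side by side. Read counts per library were not used here, so the depth behind each value is unknown, and intervals on shares are Wilson 95% intervals that cover counting error over peaks or genes alone.

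Regions were read 1-based in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Genes and transcript 5′ ends came from the Ensembl release 115 annotation of WBcel235, and sequence from the reference genome of the same build. A promoter window ran from 1000 bp upstream to 300 bp downstream of the 5′ end of any protein-coding transcript. A gene counted as carrying a promoter peak when an IDR summit lay in its window, so a peak between divergent genes counted for both. Background regions were the 26151 pooled relaxed regions that overlapped no IDR peak by 1 bp or more. Shares of IDR peaks in promoter windows, on X, in autosome centres (25% to 75% of each length) and with a motif were compared with background regions by two-sided Fisher's exact tests. Motifs were the cell cycle genes homology region (CHR) element TTYGAA, the site bound by LIN-54, and the E2F site TTSSCGC, bound by the partner subunits EFL-1 and DPL-1, on either strand within 50 bp of a summit. Centring was tested with a two-sided exact binomial test of motif centres within 50 bp of summits against those 150 to 200 bp away. Overlapping matches on opposite strands counted as separate sites, so the centres are not fully independent. Motif shares were also set beside 10 dinucleotide shuffles of the same sequences, and promoter shares beside 1000 random placements on the same chromosomes.

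Replicates were compared through the 3449 strongest regions of each relaxed list, with an overlap of at least 50% of the shorter region, and through correlations across IDR peaks found in both lists, which are not independent replicates. 20 gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 20 lists. With the exceptions given below, lists, motifs, windows, tests and the rule for named genes were fixed before the data were examined. That rule took the nearest genes of the 8 strongest IDR peaks, every subunit of the DREAM complex, the 3 members with the strongest promoter peak in each of the mitotic, replication, meiotic, germline RNA and small RNA lists, and every bound member of lists with 5 or fewer. Other genes are named as examples chosen after their values were seen. Also chosen after values were seen were the count of peaks near tRNA genes and the count of relaxed regions near lin-54. The same holds for the E2F share of ribosomal protein promoter peaks. Of the listed symbols, 8 matched no protein-coding gene of the annotation (smc-1, rad-54, fcd-1, rde-3, hsp-16.49, hsp-16.11, daf-21 and opt-2) and were left out.

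Alternatives were the strongest 1724 IDR peaks, each replicate left out in turn with the strongest 3449 regions of the other used as the peak set, narrower and wider promoter windows, other motif distances, a GC-matched background, promoter windows only, other overlap rules, each peak assigned to its nearest gene, and a gene background limited to genes with a relaxed region in the promoter window. After the data were seen, 3 were added: leaving out peaks within 200 bp of tRNA genes, promoter windows with GC matching, and 10000 rotations of the promoter peak flags along the gene order. The list test was tested on simulated data over 19973 genes: 2.75% of 400 tests of random lists passed an unadjusted 0.05, and lists of 40 genes were recovered in 3 of 5 cases when 30% of members were bound and in 5 of 5 cases at 50% and 80%. The simulated lists were drawn gene by gene at random, so they do not cover lists of neighbouring genes. The motif search found 25.0% of 881 shuffled sequences without an E2F site positive after the site was planted in 25%, which checks the search alone. With 1 group, no comparison between conditions was possible.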

Results

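LIN-54 is the subunit of the DREAM complex that contacts the CHR element in DNA. DREAM joins it to the E2F protein EFL-1, its partner DPL-1 and the Rb-like protein LIN-35, and is known for repressing cell cycle genes. Its binding sites were mapped by anti-GFP ChIP-seq in whole young adult worms of mixed sex, 65 hours of age, of a transgenic strain with tagged LIN-54. The 2 biological replicates form 1 group, so the questions are where LIN-54 bound, how well the replicates matched, and which genes and motifs lay at the peaks. The IDR list held 3449 peaks with a median width of 336 bp and a median signal of 177, between 98.2 and 7882. These were exactly the 3449 strongest of the 30000 pooled relaxed regions. Read depth is unknown.

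The first comparison asks how far the replicates identified the same sites. The strongest peak in each replicate and in the pooled list lay upstream of rpl-3, a large ribosomal subunit gene, with signals of 4005 in replicate 1 and 3909 in replicate 2. The promoters of rpl-35 and tasp-1, a threonine aspartase gene, ranked 2 and 3 in both. Of the 3449 strongest regions of replicate 1, 2605 (75.5%, 95% interval 74.1% to 76.9%) met one of the 3449 strongest of replicate 2, against 1.25% ± 0.192 (SD over 1000 random placements). Of the IDR peaks, 2572 (74.6%) were met in the strongest sets of both replicates, 789 in exactly 1 and 88 in neither, while 3396 (98.5%) were present in both full relaxed lists. Across those 3396 peaks, signals in the replicates had a Spearman's rho of 0.806 and a Pearson's r of 0.882 on the log10 scale. Peaks are not independent replicates, so no p-value is given. The IDR peaks were also selected from these same replicates, so their presence in both lists and their correlation are no independent test of agreement. The share of pooled regions found in both replicate lists was 99.6% for ranks 1 to 1000 and 4.70% for ranks 29001 to 30000.

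**Figure D1:**
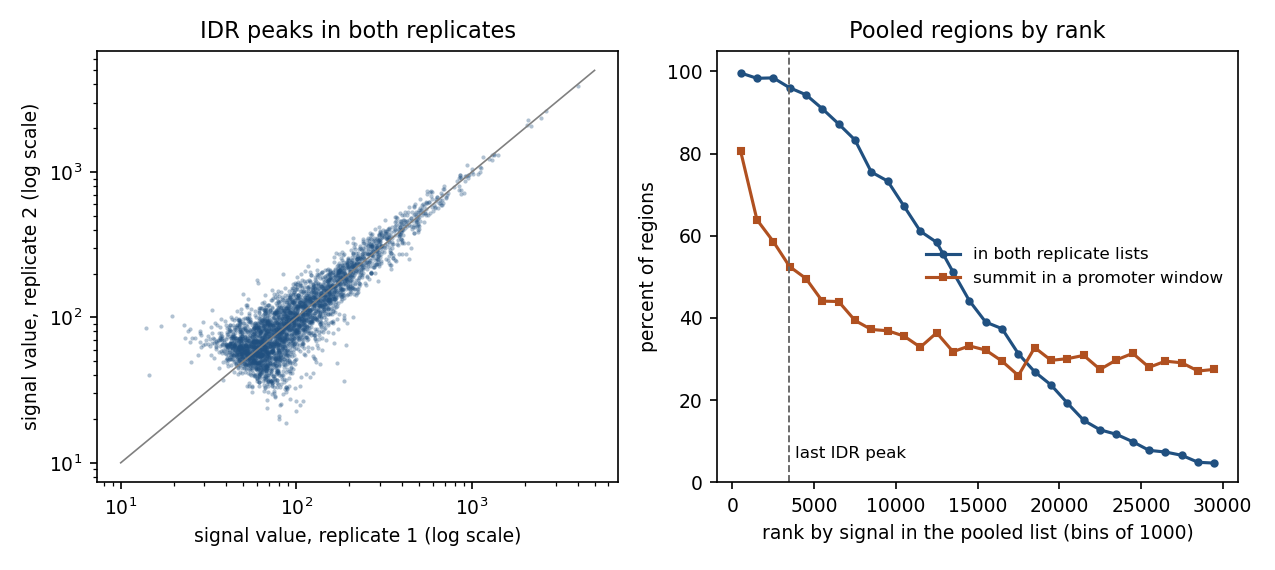
Left, signal value of each of the 3396 IDR peaks found in both relaxed lists, replicate 1 against replicate 2, on log axes with the line of equal values; right, percent of pooled regions in both replicate lists and percent with the summit in a promoter window, per 1000 ranks by signal. The strongest peaks lie close to the line, and both percentages fall with rank, from 99.6% and 80.6% in the first 1000.

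The second comparison asks where in the genome the peaks lay. LIN-54 peaks sat mainly just upstream of protein-coding genes: 2281 of 3449 (66.1%, 64.5% to 67.7%) had the summit in a promoter window, against 8683 of 26151 background regions (33.2%, odds ratio 3.93, Fisher's exact p = 2.06e-298). Random placement gave 28.1% ± 0.761 (SD). The median summit position relative to the nearest 5′ end was -180 bp, with quartiles at -345 and -78 bp, negative being upstream. Coding exons outside promoter windows held 2.87% of IDR peaks and 24.9% of background regions, introns 10.3% and 24.1%, and intergenic sequence 18.03% and 13.9%. Outside promoter windows, 188 peaks lay within 200 bp of a tRNA gene. In all, 2859 of 19973 protein-coding genes (14.3%) had a promoter peak. Of the promoter peaks, 801 (35.1%) lay in windows of several genes, so the gene served by such a peak cannot be read from its position.

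Among the 8 strongest peaks, after rpl-3 (signal 7882, chromosome III, 3867274 to 3867802), rpl-35 (5249, III, 7854458 to 7854889) and tasp-1 (4812, III, 10759041 to 10759486) came cdc-48.1, a AAA ATPase gene (4348, II, 10563354 to 10563769), and sec-61.G, a translocon subunit gene (4230, V, 10897148 to 10897615). A peak between the divergent genes rpl-12 and lin-54 itself followed (4155, IV, 13240425 to 13240871), then those of tba-2, an alpha tubulin gene (2725, I, 12966725 to 12967245), and eef-2, an elongation factor gene (2670, I, 9163325 to 9163727). All 8 summits were intergenic, at positions from -456 bp (rpl-35) to -18 bp (eef-2) relative to the 5′ end, and all ranked among the first 9 in each replicate. The peaks named for tasp-1, sec-61.G and eef-2 also lay in the windows of K01G5.10, F32D8.13 and clsp-1. The strain carries a further lin-54 locus on its transgene, and 28 relaxed regions lay within 20 kb of the lin-54 start.

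Across chromosomes, peaks were densest on III (53.5 per Mb) and I (47.8 per Mb) and sparsest on X (14.4 per Mb). X held 255 of the 3449 peaks (7.39%, 6.57% to 8.31%) and 13.7% of protein-coding genes. Against the background regions, of which 8.28% lay on X, the difference did not pass the threshold (Fisher's exact p = 0.0796). It did among the strongest 1724 peaks, of which 5.28% lay on X (Fisher's exact p = 3.87e-06), and with either replicate alone, at 8.96% against 10.9% for replicate 1 and 6.84% against 8.65% for replicate 2 (Fisher's exact p = 0.000428 and 0.000261). On autosomes, 1866 of 3194 peaks (58.4%, 56.7% to 60.1%) lay in the middle 25% to 75% of the chromosome, against 50.3% of background regions (Fisher's exact p = 6.57e-18).

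The third comparison asks whether the sequence elements of DREAM lay at the peaks. The E2F site was found within 50 bp of 593 summits (17.2%, 15.97% to 18.5%), against 5.81% of background regions (odds ratio 3.37, Fisher's exact p = 1.46e-102) and 8.53% ± 0.593 of shuffled sequences (SD over 10 shuffles). The CHR element was found at 1153 summits (33.4%, 31.9% to 35.0%), against 26.3% of background regions (odds ratio 1.41, Fisher's exact p = 5.10e-18) and 19.9% ± 0.321 of shuffled sequences. E2F sites were concentrated at summits, with 706 centres within 50 bp and 142 in the flanks (83.3%, exact binomial p = 1.22e-90). CHR elements were only slightly so by this test, with 1460 against 1341 (52.1%, exact binomial p = 0.0258), and without replicate 2 this value was 51.6% (exact binomial p = 0.109). The test assumes an even split, which background regions did not have. Per 1000 background regions and 25 bp bin, CHR elements numbered 83.7 to 87.3 within 50 bp of the summit and 97.4 to 98.9 in the flanks. E2F sites numbered 17.2 to 18.7 and 11.9 to 12.9. Relative to background regions, the test therefore understates the centring of CHR elements and overstates that of E2F sites. CHR elements were most frequent 25 to 50 bp to either side of the summit (121 and 132 per 1000 peaks) and less frequent within 25 bp (78.9 and 91.9), and within 25 bp the share of peaks with one was 13.98% against 14.13% in background regions. Background regions had 86.6 and 83.7 per 1000 within 25 bp, and 83.9 and 87.3 at 25 to 50 bp. They were thus evenly low within 50 bp of the summit, without the drop from 25 to 50 bp to the summit found in IDR peaks.

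Both elements lay at several named promoters. Near the summit at pcn-1, the gene of the replication clamp PCNA, the CHR sequence TTCAAA (IV, 4049675 to 4049680) was centred at -19.5 bp from the summit and the E2F sequence TTCGCGC (IV, 4049654 to 4049660) at -40 bp, on plus strand coordinates. The reference sequence of that window (plus strand, IV, 4049647 to 4049747) is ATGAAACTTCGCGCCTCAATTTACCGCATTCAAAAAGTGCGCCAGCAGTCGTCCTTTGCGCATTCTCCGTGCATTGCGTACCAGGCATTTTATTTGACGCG. The summits at tba-2 and eef-2 each had 3 E2F matches and 1 CHR element within 50 bp. At tba-2 the matches TTCGCGC (I, 12966897 to 12966903) and GCGCCAA (I, 12966900 to 12966906) overlap on opposite strands. The summits at rpl-3, rpl-35 and rpl-12 had a CHR element and no E2F site, and that at cdc-48.1 had neither.

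**Figure D2:**
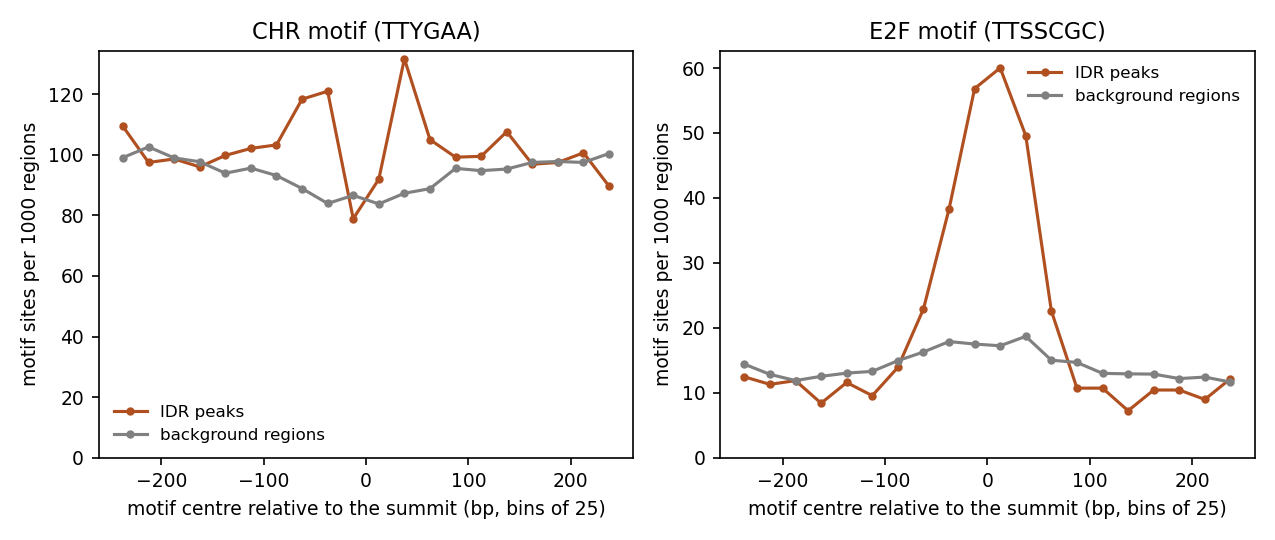
Sites of the CHR element (left) and the E2F site (right) per 1000 regions, in bins of 25 bp around the summit, for the 3449 IDR peaks and the 26151 background regions. E2F sites peak at the summit of IDR peaks, while CHR elements are highest 25 to 50 bp away on both sides and low at the summit.

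The fourth comparison asks which gene groups carried LIN-54 at the promoter. LIN-54 lay at most genes of the DREAM complex: 7 of the 8 subunit genes had a promoter peak (87.5%, 52.9% to 97.8%), against 14.3% of other genes (adjusted Fisher's exact p = 1.56e-05). With each peak given to its nearest gene, 62.5% had one. The peaks of lin-9 (III, 8904053 to 8904451, signal 1589, 840 in replicate 1 and 757 in replicate 2) and lin-53 (I, 9619843 to 9620147, 1302, 631 and 671) ranked 37 and 53. That of efl-1 (V, 16965703 to 16965988, 976, 469 and 506) ranked 108 and that of lin-35 (I, 5807418 to 5807674, 513, 279 and 221) ranked 378. The peaks of dpl-1 (II, 9169495 to 9169830, signal 131, rank 2415) and lin-52 (III, 9824562 to 9824897, signal 129, rank 2451) were much weaker, and the lin-54 peak is the one shared with rpl-12. The strongest region at lin-37 (III, 7072308 to 7072643, signal 59.8) ranked 6949 and was not an IDR peak. The efl-1, lin-35 and lin-53 peaks also lay in the windows of fbxa-90, vps-51 and nra-2.

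Cell cycle genes carried LIN-54 at most of their promoters. A promoter peak was present at 67 of 90 mitotic genes (74.4%, 64.6% to 82.3%, adjusted Fisher's exact p = 4.81e-37) and at 49 of 70 genes of DNA replication and repair (70%, 58.5% to 79.5%, adjusted Fisher's exact p = 2.55e-25). The strongest mitotic members were the kinetochore genes knl-3 (V, 1868649 to 1868968, signal 1483), kbp-4 (III, 1080603 to 1080902, 1147) and hcp-4 (I, 3866480 to 3866772, 1143), each with an E2F site near the summit. The strongest replication members were pcn-1 (IV, 4049482 to 4049954, signal 2498, 1296 in replicate 1 and 1215 in replicate 2), top-2, the topoisomerase II gene (II, 11874712 to 11875057, 1258), and rfc-4, a clamp loader gene (III, 6971932 to 6972256, 1186). The peaks of top-2 and rfc-4 also lay in the windows of npp-3 and eef-1A.1, and those of the 3 kinetochore genes in windows of neighbours. The mitotic genes without a promoter peak included cdk-4, cyd-1, cki-1, fzy-1 and air-1.

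Germline genes also carried LIN-54 more often than other genes. A promoter peak was present at 32 of 58 germline RNA regulators and oocyte factors (55.2%, 42.5% to 67.3%, adjusted Fisher's exact p = 1.32e-12), led by cgh-1, a germline RNA helicase gene (III, 7498418 to 7498808, signal 1378), ifet-1 (III, 4475502 to 4475801, 1047, shared with rps-1) and egg-1 (III, 5727827 to 5728145, 801). It was present at 22 of 45 small RNA pathway genes (48.9%, 34.96% to 63.0%, adjusted Fisher's exact p = 7.99e-08), led by rde-2 (I, 7283692 to 7284001, signal 1203), nrde-2 (II, 10248444 to 10248694, 554) and the nuclear Argonaute gene hrde-1 (III, 4176275 to 4176512, 487). These 3 peaks also lay in the windows of pfd-6, atad-3 and C16C10.13, and with each peak given to its nearest gene the small RNA share was 28.9% (adjusted Fisher's exact p = 0.00104). Of the 40 genes listed as meiotic chromosome factors, 17 had one (42.5%, 28.5% to 57.8%, adjusted Fisher's exact p = 2.32e-05). The strongest listed member was lin-5 (II, 7860167 to 7860640, signal 619), a spindle gene rather than a chromosome factor. The cohesin genes coh-3 (V, 14457153 to 14457397, 545) and coh-4 (V, 4175698 to 4175927, 537) followed, with peaks shared with bmk-1 and pid-5. Among synMuv B and other chromatin regulators, 21 of 32 had one (65.6%, 48.3% to 79.6%, adjusted Fisher's exact p = 1.30e-10), among them mes-2, a histone methyltransferase gene (signal 1065).

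Housekeeping groups, and the heat shock and stress genes, were likewise bound more often than other genes. Promoter peaks lay at 67 of 78 ribosomal protein genes (85.9%, adjusted Fisher's exact p = 2.12e-44), 24 of 33 proteasome genes (72.7%, adjusted Fisher's exact p = 2.08e-13), 17 of 26 respiratory chain genes (65.4%, adjusted Fisher's exact p = 9.11e-09), 11 of 22 spliceosome genes (50%, adjusted Fisher's exact p = 0.000119) and 10 of 24 heat shock and stress genes (41.7%, adjusted Fisher's exact p = 0.00145). Among genes with any relaxed region in the window, the difference no longer passed the threshold for meiotic factors (48.6% against 37.6%, adjusted Fisher's exact p = 0.245), heat shock (62.5%, adjusted Fisher's exact p = 0.0888, or 0.0526 with each peak given to its nearest gene) and spliceosome genes (55.0%, adjusted Fisher's exact p = 0.196). With each peak given to its nearest gene, the ribosomal share was 55.1% (adjusted Fisher's exact p = 3.29e-21) and the spliceosome share 27.3% (adjusted Fisher's exact p = 0.0377). Of the ribosomal protein promoter peaks, 4 of 64 (6.25%) had an E2F site, against 21.2% of other promoter IDR peaks.

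Lists of genes used in differentiated tissues had few promoter peaks. Promoter peaks lay at 19 of 1364 chemoreceptor genes (1.39%, 0.894% to 2.17%, adjusted Fisher's exact p = 7.33e-66) and 5 of 156 collagen genes (3.21%, 1.38% to 7.28%, adjusted Fisher's exact p = 1.56e-05), namely col-2, col-38, col-63, col-71 and col-185. Among genes with any relaxed region in the window the differences were smaller, at 24.7% of 77 chemoreceptor genes (adjusted Fisher's exact p = 0.0357) and 12.8% of 39 collagen genes (adjusted Fisher's exact p = 0.00227), against 37.8% of other genes for both. None of the 31 major sperm protein genes had one (0%, upper bound 11.03%, adjusted Fisher's exact p = 0.0229), a difference lost in 5 alternatives, among them rotation of the gene order (adjusted rotation p = 0.101) and genes with any relaxed region, where 2 were left (adjusted Fisher's exact p = 0.553). Shares at or below 6.25% were also found for muscle (unc-45 and unc-112 of 38), neuron (ric-19, snb-1 and unc-31 of 48), intestine (asp-1 of 29) and HOX and vulval signalling genes (glp-1 of 23), none past the threshold (adjusted Fisher's exact p = 0.168, 0.162, 0.140 and 0.238). Without replicate 1 the muscle and neuron differences passed it (adjusted Fisher's exact p = 0.0443 and 0.0462), as did the intestine difference among genes with any relaxed region (adjusted Fisher's exact p = 0.0391). Histone genes, with 15 of 72 (20.8%), did not differ detectably from other genes (adjusted Fisher's exact p = 0.150), and the direction turned in 2 alternatives. Only 26 of the 72 had any relaxed region in the window. Of these, 57.7% had a promoter peak, against 37.6% of other such genes (adjusted Fisher's exact p = 0.0603).

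**Figure D3:**
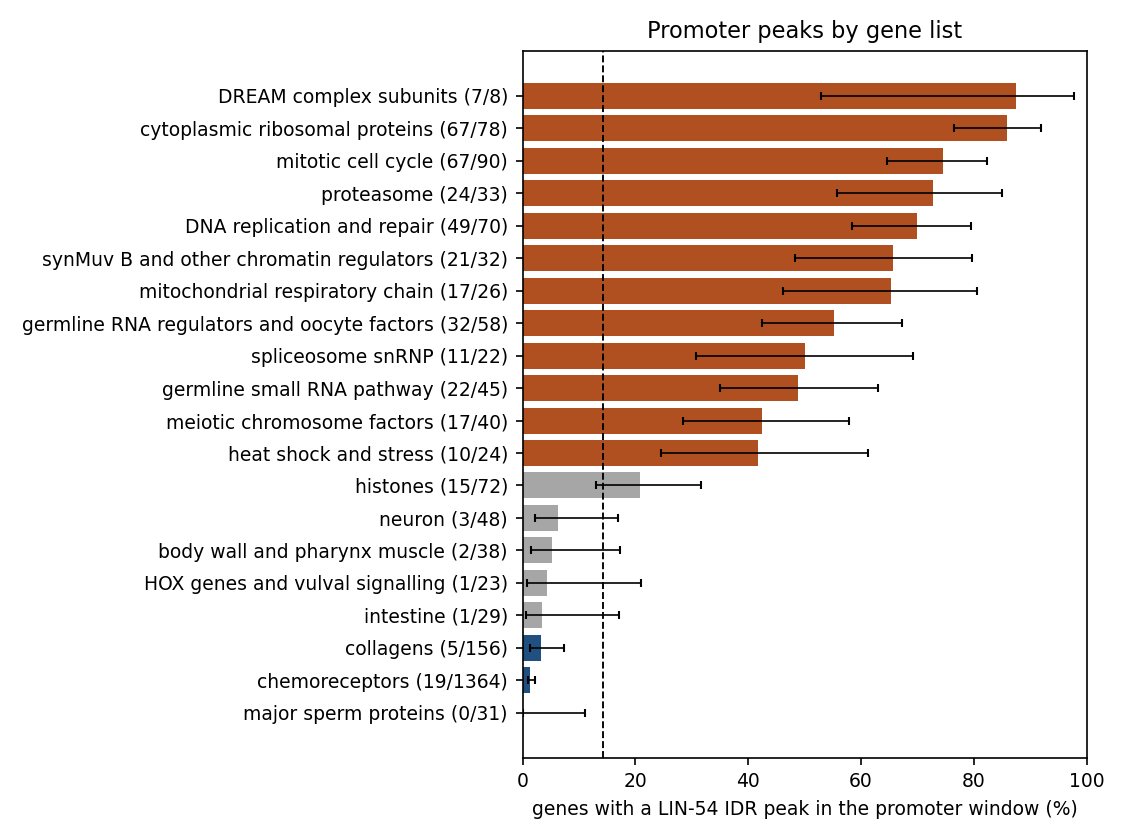
Percent of the genes of each of the 20 lists with an IDR peak in the promoter window, with Wilson 95% intervals, bound and total genes in brackets, and the share of all protein-coding genes (14.3%) as a dashed line. Orange bars lie above other genes and blue bars below them at an adjusted p under 0.05, and grey bars did not pass; the list of major sperm proteins, at 0 of 31, also passed.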

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

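Of the tests in this part, the count of relaxed regions near lin-54, the scan of noncoding genes and the comparison of ribosomal protein peaks with other promoter IDR peaks were chosen only after the result was seen.

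IDR peaks lay at noncoding RNA genes, for which the comparisons above gave only the count of tRNA gene peaks outside promoter windows. Of the 3449 peaks, 254 (7.36%) had a summit within 200 bp of a tRNA gene, against 0.424% of background regions (Fisher's exact p = 4.80e-151). They covered 282 of 612 tRNA genes (46.1%, 42.2% to 50.04%). Near snoRNA genes lay 98 peaks (2.84% against 0.352%, Fisher's exact p = 1.32e-41) and near snRNA genes 47 (1.36% against 0.0994%, Fisher's exact p = 1.91e-26). Each type was counted separately, so a peak may count for several types. Outside promoter windows lay 61 of the snoRNA gene peaks and 23 of the snRNA gene peaks. Near miRNA and piRNA genes the shares did not differ past the threshold (Fisher's exact p = 0.0716 and 0.0962).

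For the tRNA gene peaks, neighbouring protein-coding promoters are argued against as the whole source, since 25.98% of the peaks (20.98% to 31.7%) lay in promoter windows, against 69.3% of other IDR peaks. Reads shared between copies are not settled: 42 of 143 tRNA genes of unique sequence had a peak (29.4%, 22.5% to 37.3%), above the 14.3% of protein-coding genes with a promoter peak. Genes with a shared sequence had one more often (51.2%, Fisher's exact p = 3.94e-06). Unique means that no other tRNA gene had the identical sequence, so reads could still be shared with near-identical copies. A summit within 200 bp counted, so it could belong to a neighbouring tRNA gene, and the 14.3% rests on a different window. Unspecific pull-down at highly transcribed genes stays open: with tRNA genes masked, which shortens the sequence searched, 3.15% of these peaks had an E2F site (1.60% to 6.09%), against 5.79% of background regions, and unmasked 6.30% had one (3.91% to 9.99%), against 5.81%, both below the 18.1% of other IDR peaks. Binding without the motif would give the same share, and no ChIP without the tag was used here. The design has no other group, so no biological explanation was tested.

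Ribosomal protein promoters held ranks 1, 2 and 6 among the 8 strongest peaks, although the median signal of the bound ribosomal genes, 281, lay between that of all bound genes, 222, and that of bound mitotic genes, 329. Each of these 3 peaks had a CHR element within 50 bp of the summit. For the ribosomal protein promoter peaks as a set, a candidate explanation is that open promoters were pulled down without the motifs: 17 of 64 (26.6%, 17.3% to 38.5%) had a CHR element or E2F site, not above the 30.5% of background regions in promoter windows and below the 47.4% of other promoter IDR peaks. This set is wider than the strongest peaks, for which the explanation was not tested. Binding through other sequences or partners would give the same values, and no biological explanation was tested.

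The peak between rpl-12 and lin-54 could carry extra reads from copies of the lin-54 fosmid in the strain. Within 20 kb of the lin-54 start lay 28 relaxed regions, where the median autosomal gene with a promoter peak had 20, and 22.1% of those genes had as many. The unc-119 locus, also carried by the transgene, had 8, but unc-119 had no promoter peak, so that median does not apply to it. The excess is too small to decide, and without coverage values or the ends of the fosmid the copies and a strong native site cannot be told apart.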

How the results depend on the processing

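Alternatives without the tRNA gene peaks, with GC matching in promoter windows, and with rotated gene order were chosen after seeing the data. Of 307 comparisons of a result with an alternative, 281 kept the direction and side of the threshold or, without a test, the value within its 95% interval, the count of lists within 1.5 times or the named gene's side of rank 3449, 10 were weaker, 8 stronger, 3 reversed and 5 moved. The CHR share reversed within 25 bp of the summit (13.98% against 14.13%, exact p = 0.835). The histone share, above other genes as reported, lay below them among the strongest 1724 peaks (4.17% against 8.91%) and in the narrow promoter window (6.94% against 11.5%), in no case past the threshold. The X share, not past the threshold as reported, was lower than background past it among the strongest 1724 peaks (5.28%), in promoter windows (4.30%) and without tRNA gene peaks (5.29%, exact p = 4.89e-09), of which 86 of 254 lay on X. The causes were not tested further. Replicate overlap was 65.5% for summits within 50 bp and 88.8% for the strongest 500 regions, and rho was 0.844 for summits within 50 bp and 0.841 for the strongest 1724 peaks. With 1 replicate left out, ranges were 64.6% to 65.9% for promoters, 6.84% to 8.96% for X (past the threshold in both, against 8.65% and 10.9%), 59.1% to 59.5% for autosome centres, 31.3% to 34.4% for CHR and 15.9% to 17.02% for E2F shares. They were 51.6% to 52.9% for CHR centring, which was no longer past the threshold without replicate 2, and 82.4% to 84.9% for E2F centring. In both cases 12 lists lay above other genes, and 3 to 5 below. Promoter, E2F and autosome centre shares kept their side in every alternative run, with E2F shares between 9.63% (within 25 bp) and 22.9% (strongest 1724 peaks). Limiting genes to those with a relaxed region left 9 lists above, against 12 as reported, and 3 below. Ranks could move within a side: lin-37, 6949 in the pooled list, ranked 10203 and 10295 in the single replicates. The collagen share was 1.28% with each peak given to its nearest gene. With 1 replicate left out, the intestine share was 6.90% to 10.3%, against 3.45% as reported, the HOX and vulval signalling share 0% to 8.70%, against 4.35%, and the muscle share 2.63% to 7.89%, against 5.26%. Of these only the muscle share without replicate 1 passed the threshold. No paired analysis was possible because there is 1 group. Depth limits are unknown, as read counts were not used here.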

Other observations

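The scan of gene classes, the hexamer counts, the X chromosome gene test, the count of shared regions below the threshold, the test of motif spacing against background regions and the tests of single offsets were chosen only after the results were seen.

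Gene classes of at least 8 members sharing a symbol were scanned, with p-values adjusted over all 240 classes. Of the 174 classes with no gene in a fixed list, 15 were bound more often than other genes and 13 less often, at an adjusted p under 0.05. Nucleoporin genes stood out, with promoter peaks at 19 of 26 npp genes (73.1%, 53.9% to 86.3%, adjusted Fisher's exact p = 1.24e-09), npp-19 having the strongest (signal 1341). SR splicing factor genes (rsp, 7 of 8, adjusted Fisher's exact p = 0.000121), chaperonin genes (cct, 6 of 8, adjusted Fisher's exact p = 0.00177), translation initiation factor genes (eif, 15 of 25, adjusted Fisher's exact p = 4.39e-06), mitochondrial large ribosomal subunit genes (mrpl, 21 of 41, adjusted Fisher's exact p = 7.71e-07) and vacuolar sorting genes (vps, 16 of 31, adjusted Fisher's exact p = 1.94e-05) were also bound often. The mitochondrial small ribosomal subunit genes (mrps, 8 of 29) did not pass the threshold (adjusted Fisher's exact p = 0.159). Nuclear hormone receptor genes (nhr, 12 of 269, adjusted Fisher's exact p = 4.91e-06), C-type lectin genes (clec, 8 of 240, adjusted Fisher's exact p = 7.71e-07) and F-box genes of the fbxa class (4 of 170, adjusted Fisher's exact p = 4.91e-06) were rarely bound.

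At the level of genes, X was sparsely bound. Promoter peaks lay at 102 of 2731 X genes (3.73%, 3.09% to 4.51%), against 2757 of 17242 autosomal genes (15.99%, odds ratio 0.204, Fisher's exact p = 2.16e-83). Among regions in promoter windows the gap was smaller, with 4.30% of IDR peaks and 7.04% of background regions on X. Bound X genes included the chaperone gene hsp-3 (signal 373) and the RNA-binding protein gene puf-9 (signal 369). Of the 254 tRNA gene peaks, 86 (33.9%) lay on X, as did 276 of 612 tRNA genes (45.1%), while 169 of the 3195 other IDR peaks (5.29%) did.

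Against a background matched for GC content, the 12 leading hexamers of 2080 all held GCGC or CGCG, led by ACGCGC (13.9% of IDR peaks and 2.97% of 11853 background regions, adjusted Fisher's exact p = 6.28e-109). TTCAAA, the form of the CHR element at pcn-1 and lin-9, ranked 22 (27.6% and 16.08%, adjusted Fisher's exact p = 2.84e-47). The palindromic form TTCGAA ranked 318 (7.80% and 5.07%, adjusted Fisher's exact p = 2.81e-08).

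The hypothesis that LIN-54 peaks prefer a fixed spacing of both elements was tested. In IDR peaks the CHR element started 6 or 7 bp upstream of the E2F site in 141 of 1242 pairs within 100 bp of a summit, against 39 pairs at 15 bp upstream, the next most frequent offset within 40 bp. This share (11.4%, 9.71% to 13.2%) did not differ detectably from the 10.8% in background regions (Fisher's exact p = 0.575) or the 10.1% at random positions outside relaxed regions (Fisher's exact p = 0.231). Per region, such pairs numbered 40.9 per 1000 IDR peaks, 20.4 per 1000 background regions and 9.18 per 1000 random positions. Taken singly against background regions, 7 of 69 offsets within 40 bp made up a larger share of the pairs in IDR peaks and 3 a smaller one, at an adjusted p under 0.05. The larger shares included those with the CHR element 6 bp upstream (5.15% against 3.16%, adjusted Fisher's exact p = 0.0150), 13 bp upstream (1.05% against 0.182%, adjusted Fisher's exact p = 0.00227) and 10 bp downstream (1.21% against 0.223%, adjusted Fisher's exact p = 0.00182). Overlapping E2F matches on opposite strands counted separately, so 1 CHR element can enter both at 6 bp upstream and at 10 bp downstream. Offsets are therefore not independent, and whether the excess was particular to 6 bp cannot be told. The share 7 bp upstream did not differ detectably (6.20% against 7.63%, adjusted Fisher's exact p = 0.244).

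Below the IDR threshold, 270 background regions met regions outside the IDR set among the strongest 5000 of both replicates, against a mean of 23.2 over 20 random placements. Pooled regions come from the reads of both replicates, so an excess over random placement was built in and shows no binding by itself. They added promoter regions at 122 genes without an IDR promoter peak, among the fixed lists zhp-1, daf-16, fat-6, pbs-3 and rpt-4. The 270 regions lay in promoter windows more often than other background regions (52.6% against 33.0%, Fisher's exact p = 4.68e-11). Pooled regions of ranks 3001 to 4000 and 4001 to 5000 had 52.5% and 49.6%, so this difference cannot be told apart from one of rank. Neither motif was detectably more frequent in them, with E2F sites in 7.04% against 5.80% (Fisher's exact p = 0.360) and CHR elements in 21.1% against 26.4% (Fisher's exact p = 0.0518).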
